A study of Schmidtea mediterranea with 15 samples.

How the data were processed

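Whole adult planarians of the clonal CIW4 line of Schmidtea mediterranea, a freshwater flatworm, were profiled by sequencing of polyA RNA, with Illumina TruSeq libraries per the labels' protocols. The labels place 15 libraries in 5 groups of 3, which are unirradiated worms (0 h) and worms at 24, 48, 72 and 96 h after 6000 rad of gamma radiation. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be partly technical. The labels of all 15 samples name whole worm tissue as the source, while the library protocol they share also gives an input for sorted cells, and the source was taken from the former. The labels give unirradiated worms at 0 h only. Irradiation, elapsed time and any handling or library batch that goes with them therefore cannot be told apart.

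The authors deposited RPKM values, reads per kilobase of transcript model scaled to library size, for 26671 transcript models in each of the 15 libraries. The submitters' processing notes name CASAVA 1.8.2, Bowtie and edgeR as the authors' tools, with no version for the last 2 and no role or order. The transcript set, the mapping settings, the use of strand and the treatment of reads that match several models are not given in the sources used here. Reads from near-identical, overlapping or antisense models may thus be shared between them, and models are treated as separate features. RPKM is relative to the reads of its own library, so a change in the amount of RNA per worm does not show in it.

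The deposited RPKM values were whole multiples of a step set by the length of the model and by the library. From these steps the library divisors, the lengths and the whole reads were worked out, using 1136 models under 0.5 RPKM in every library to set the relative depths. All 26671 models (100%) came out at whole reads in all libraries, within a tolerance of 0.001 reads. Lengths ran from 60 to 23779 bases with a median of 1042 bases. The recovered reads per library ranged from 9749391 to 30707808. The divisors were 0.974 to 1.027 times the recovered reads and these ratios had a geometric mean of 1, so the deposited values carry a scaling between libraries beyond the plain read totals. Each model had at least 31 recovered reads over the 15 libraries and a value above 0 in at least 4 of them. The same recovery gave exact reads for 100% of 3977 simulated models. These lengths and reads were worked out here from the values.

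Each value was transformed as log2(RPKM + 0.5) with no further rescaling. Models with at least 1 RPKM in at least 3 of the 15 libraries were tested, 21231 in all (79.6%). A linear model with a mean per time point was fitted to all 15 libraries with limma 3.58.1 in R 4.3.3, with moderated variances that follow a trend with level. All contrasts were two-sided. A model was called when its Benjamini-Hochberg adjusted p within a contrast was below 0.05. Changes are on the log2(RPKM + 0.5) scale, which understates the change of models at low levels. The planned contrasts were each irradiated time against 0 h and each time against the one before, plus an F test over the 5 time points. A contrast of 96 h with 24 h was added after seeing the data. Models that were called and at least 2-fold lower (or higher) than at 0 h were assigned to the earliest time at which this held. Shares of reads are percentages of the recovered reads of a library. Figures were drawn with matplotlib 3.10.9, and tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.

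A set of 22 gene lists (stem cell, epidermal progeny, tissue and pathway markers) was fixed before the data were examined. The deposited table pairs no ID with a gene name and no name table was used here, so no list was tested and no cell type or pathway is attached to any group of models. With no names, the rule fixed for naming features gave the 2 models with the largest falls and the 2 with the largest rises over the 4 contrasts with 0 h. These came from called models whose 3 values all lay beyond the 3 values at 0 h and whose mean reached 5 RPKM in the higher group. All other models are given as counts, small counts included.

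The limma step was tested on simulated reads for the comparison of 24 h with 0 h over 21296 tested models. It called 8 of 48 models changed 1.2-fold, 32 of 49 changed 1.5-fold, 38 of 47 changed 2-fold and 48 of 50 changed 4-fold, with 0 in the wrong direction. It also called 23 unchanged models, 15.4% of its calls, with a median of 57 reads over the 0 h libraries against 311 for all tested models. For limma-voom on the same simulated reads these were 9 models, 6.57% of calls and a median of 13 reads. In this simulation the share of unchanged models among the calls was above the adjusted p of 0.05 for both. Only 194 of the tested models were changed in it. The share therefore cannot be read as that among the real calls, which were far more numerous.

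Replicates of a group differed by more than sampling noise. Over models with at least 20 reads in the pair, the mean chi-square of the 15 replicate pairs ran from 1.49 to 5.94, while sampling alone stays below about 1.02. No pair thus looked like a library deposited again, and all 15 were counted separately, which does not show whether they came from separate worms.

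The alternatives chosen before the data were examined were pseudocounts of 0.1 and 1 RPKM, no filter on low values, rescaling by median of ratios or by quantiles, robust variance moderation, fits to only the 6 libraries compared, a stricter adjusted p of 0.01, a required 2-fold change, the replicate number as a block and leaving out each library in turn. Limma-voom on the recovered reads, thinning of the reads to the shallowest library and removal of each library's trend with length were added after seeing the data. The main test is not a count test, because RPKM values are not counts.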

Results

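Transcript levels were measured in whole planarians over 4 days after gamma irradiation, to follow how gene expression changes with time after the exposure. Planarians hold a population of dividing stem cells, the neoblasts, which are known to be sensitive to ionising radiation. Unirradiated worms (0 h) and worms at 24, 48, 72 and 96 h after 6000 rad were each represented by 3 libraries, 15 in all. The 0 h libraries held 9749391 to 13801926 recovered reads and the irradiated libraries 16435841 to 30707808, so each 0 h library was shallower than each irradiated library. A single transcript model took 10.03% to 11.8% of the reads of a library. Of 26671 transcript models, 21231 reached at least 1 RPKM in at least 3 libraries and were tested. The models carry IDs without gene names, so they are described by how and when their levels changed.

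The libraries grouped by time point along the 2 leading components of the log2 values, although no single component separated all 5 groups. The 72 h and 96 h libraries overlapped on the first, and the 72 h libraries overlapped with those at 0 h and 48 h on the second. The first component held 45.6% of the variance and placed the 0 h libraries at -51.6 ± 0.74 (SD, n = 3), the 24 h libraries at -0.24 ± 0.41 and the 96 h libraries at 20.2 ± 0.73. The second component held 15.3% and set the 24 h libraries (-27.6 ± 1.43) apart from those at 0 h (8.05 ± 1.57) and 96 h (17.8 ± 0.74). In limma's F test over the 5 time points, 11218 models (52.8% of those tested) changed at an adjusted p below 0.05.

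**Figure D1:**
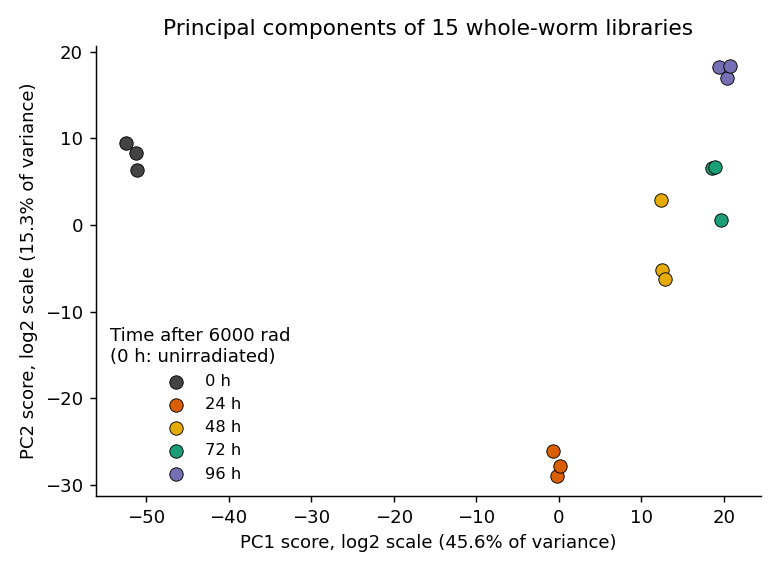
Scores of the 15 libraries on principal components 1 and 2 of log2(RPKM + 0.5), with points coloured by hours after irradiation. The 0 h libraries lie near -51.6 on the first component and the 24 h libraries near -27.6 on the second, while the 48, 72 and 96 h groups have means of 12.6 to 20.2 on the first.

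At 24 h the large changes against unirradiated worms were mostly falls. A total of 505 transcript models fell at least 2-fold and 41 of these at least 8-fold, whereas 43 rose at least 2-fold. The 505 falling models, chosen for their fall, together took 1.41% ± 0.00348 of reads at 0 h and 0.485% ± 0.00802 at 24 h (SD, n = 3). With no limit on size, 4115 models were higher and 4430 lower at 24 h (limma, adjusted p below 0.05), and 77.5% of these calls were changes of less than 1.5-fold. The median change over the 21231 tested models was -0.01 on the log2 scale. The number of rises of at least 2-fold depended on the pseudocount, at 109 models with 0.1 RPKM and 22 with 1 RPKM, and was 83 with limma-voom. The number of 8-fold falls did so too, at 113 and 17, and was 125 with limma-voom.

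The 2 models with the largest rises peaked at 24 h. Both were lower at 48 h, when only SMED30013692 was no longer called against 0 h. SMED30017313 rose from 7.78 ± 1.17 RPKM at 0 h to 30.99 ± 3.30 RPKM at 24 h (SD, n = 3), a log2 change of 1.93 (SE 0.13, limma adjusted p = 1.75e-08), with all 3 libraries at 24 h above all 3 at 0 h. Its level was 15.3 ± 1.45 RPKM at 48 h, 11.8 ± 2.36 at 72 h and 10.7 ± 1.04 at 96 h. These values rest on 30 to 32 reads per library at 0 h and 155 to 278 at 24 h. At 48 h the model was still called higher than at 0 h (log2 change 0.94, SE 0.13, limma adjusted p = 3.47e-05). The same held at 72 h (log2 change 0.57, SE 0.13, limma adjusted p = 0.00225). The difference was also called at 96 h (log2 change 0.44, SE 0.13, limma adjusted p = 0.0124). That last call was lost without 0 h replicate 1 (limma adjusted p = 0.0639) and with limma-voom on recovered reads (adjusted p = 0.0599). SMED30013692 rose from 56.2 ± 1.35 to 197 ± 13.5 RPKM at 24 h, a log2 change of 1.797 (SE 0.05, limma adjusted p = 2.77e-12), again in 3 of 3 libraries. At 48 h it stood at 58.2 ± 3.79 RPKM, a change of 0.05 against 0 h that did not pass the test (limma adjusted p = 0.521). At 72 h it was lower than at 0 h, at 47.7 ± 2.39 RPKM (log2 change -0.23, SE 0.05, limma adjusted p = 0.00195). At 96 h it stood at 51.9 ± 0.625 RPKM, a difference that was not called (limma adjusted p = 0.0944), but was called after quantile normalization (adjusted p = 0.0448) and in the fit to only the 6 libraries compared (adjusted p = 0.0154).

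At 48 h against 0 h, 549 models fell at least 2-fold, 62 of them at least 8-fold, and 25 rose at least 2-fold. Of the 505 models with a 2-fold fall at 24 h, 412 also had one at 48 h. Independent lists of these sizes would share 13.1 models. Because the 3 controls cannot be divided, part of the excess may come from the shared control libraries. In all, 4360 models were higher and 4141 lower than at 0 h (limma, adjusted p below 0.05), and 78.1% of the calls were under 1.5-fold. The count of 25 rises became 48 without 0 h replicate 1, 38 without 0 h replicate 3 and 40 without 48 h replicate 3, and ranged from 12 with a pseudocount of 1 RPKM to 76 with 0.1 RPKM.

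At 72 h the falls were again the larger changes. Against 0 h, 629 models fell at least 2-fold, 66 of them at least 8-fold, and 21 rose at least 2-fold. A 2-fold fall at both 24 h and 72 h was seen in 421 models, where independent lists would share 15.0, with the same reservation about shared controls. Regardless of size, 4694 models were higher and 4574 lower (limma, adjusted p below 0.05). The count of 21 rises became 36, 32 and 46 when 0 h replicate 1, 2 or 3 was left out, and ranged from 2 with a pseudocount of 1 RPKM to 83 with 0.1 RPKM.

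By 96 h, 701 models had fallen at least 2-fold against 0 h and 65 of them at least 8-fold, while 12 had risen at least 2-fold. A 2-fold fall at both 24 h and 96 h was seen in 412 models, where independent lists would share 16.7. Part of the excess may again come from the shared controls. In simulations with no change at any time, 0 models were called lower at both 24 h and 96 h. That count does not measure the part due to shared controls, since the simulated groups held no changed models. Regardless of size, 4824 models were higher and 4718 lower (limma, adjusted p below 0.05), and 76.7% of calls were under 1.5-fold. The count of 12 rises became 45, 22 and 34 without 0 h replicate 1, 2 or 3, and 21 without 96 h replicate 1 or replicate 3. With limma and a pseudocount of 1 RPKM it was 0, and also 0 at an unadjusted p below 0.05. The highest change called at the adjusted p with this pseudocount was 0.87 on the log2 scale. With 0.1 RPKM the count of rises was 74 and with limma-voom 56. The 8-fold falls numbered 37 with 1 RPKM, 155 with 0.1 RPKM and 174 with limma-voom.

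**Figure D2:**
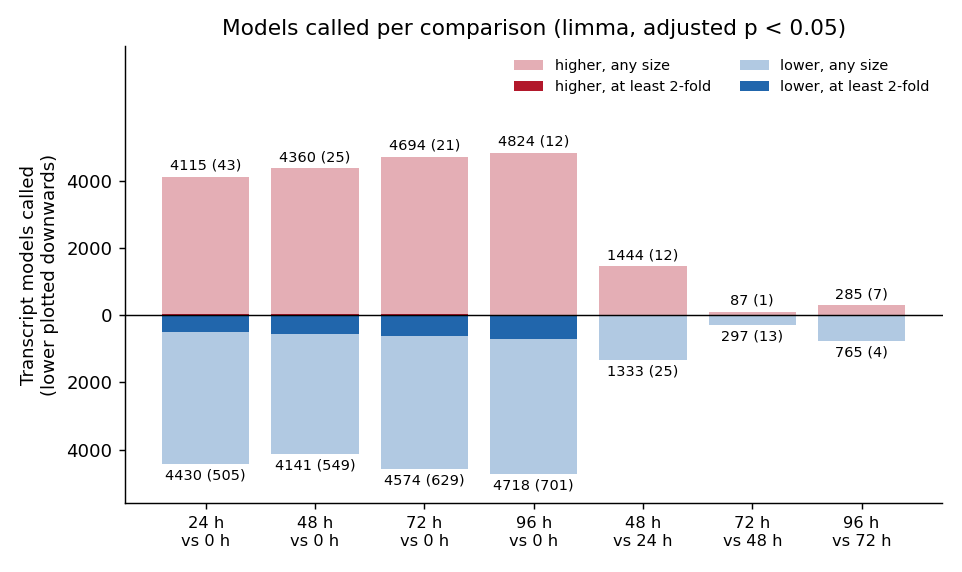
Number of transcript models called higher (plotted upwards) or lower (plotted downwards) in each comparison of time points by limma at an adjusted p below 0.05, with the number changed at least 2-fold in darker colour and in parentheses. Against 0 h, 2-fold falls numbered 505 to 701 and 2-fold rises 12 to 43.

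When each model was assigned to the earliest time at which it was at least 2-fold lower than at 0 h, 505 models were assigned to 24 h, 137 to 48 h, 103 to 72 h and 128 to 96 h. The models of the 24 h class had a median log2 change of -1.42 at 24 h, -1.53 at 48 h, -1.62 at 72 h and -1.56 at 96 h. In the contrast of 96 h with 24 h, 87 of these 505 models were lower at 96 h, 69 were higher and 349 were not called (limma). The classes of 48 h and 72 h had partly fallen before they passed 2-fold, with medians of -0.84 and -0.69 at 24 h. In the contrast of 96 h with 24 h, 65 of the 137 and 52 of the 103 models were lower at 96 h. The other 72 and 51 were not called, so a later fall was not shown for them by this contrast. The 96 h class differed from the classes of 48 h and 72 h, with a median of -0.23 at 24 h, an upper quartile of 0.44 and a median of -1.14 at 96 h. Its models together took 0.444% ± 0.000223 of reads at 0 h, 0.532% ± 0.0151 at 24 h and 0.181% ± 0.00305 at 96 h (SD, n = 3). In limma's contrast 103 of the 128 were lower at 96 h than at 24 h. The classes of 48, 72 and 96 h were chosen in these same libraries as not yet 2-fold lower at 24 h. Part of their later fall may thus come from the choice, and no held-out library was used to check it. With a pseudocount of 0.1 RPKM the 72 h class held 162 models, and with limma-voom the 48 h and 72 h classes held 226 and 161.

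Rises of at least 2-fold were fewer than falls of that size at each time against 0 h. The first 2-fold rise was at 24 h for 43 models, at 48 h for 10, at 72 h for 12 and at 96 h for 3. The median of the 24 h class went from 1.17 at 24 h to 0.91, 0.66 and 0.48 at 48, 72 and 96 h, and 29 of its 43 models were lower at 96 h than at 24 h in limma's contrast. The 3 later classes lay at medians of 0.79, 0.59 and 0.36 RPKM at 0 h, close to the pseudocount of 0.5 RPKM. Their counts changed by more than 1.5 times when single libraries were left out. Without 0 h replicate 1 they were 20, 19 and 21, without 0 h replicate 3 they were 22, 28 and 12 beside 56 at 24 h, and without 0 h replicate 2 the last was 11. The first was 20 without 48 h replicate 3, the second 22 without 72 h replicate 3, and the last 11 and 13 without 96 h replicates 1 and 3.

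**Figure D3:**
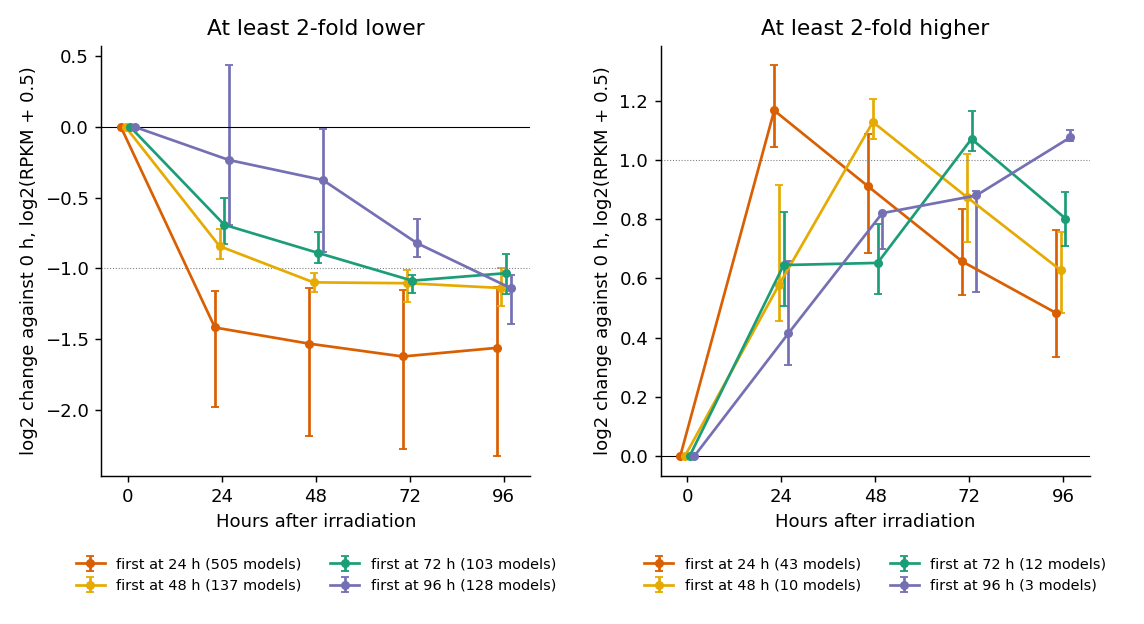
Median log2 change against 0 h of models grouped by the earliest time at which they were at least 2-fold lower (left) or higher (right), with bars from the lower to the upper quartile over models and dotted lines at a 2-fold change. The 505 models first lower at 24 h stay at medians of -1.42 to -1.62, while the 43 first higher at 24 h move from 1.17 to 0.48.

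The 65 models with falls of at least 8-fold at 96 h divided by what happened between 24 and 48 h. For 47 models no further 2-fold fall was called at 48 h, and their median log2 change against 0 h was -3.37 at 24 h, -3.44 at 48 h, -3.53 at 72 h and -3.47 at 96 h. The other 18 models were at least 2-fold lower at 48 h than at 24 h (limma, adjusted p below 0.05), with medians of -1.43, -4.89, -6.34 and -6.30. This division depends on level, because 34 of the 47 models were already so low at 24 h (median over the 47 of 0.293 RPKM) that even a fall to 0 would be less than 2-fold on the log2(RPKM + 0.5) scale, which none of the 18 were (median 13.3 RPKM). With a pseudocount of 0.1 RPKM 5 of the 47, and with limma-voom 7 of the 47, were also at least 2-fold lower at 48 h than at 24 h. Together the 18 took 0.286% ± 0.00481 of reads at 0 h, 0.0971% ± 0.000967 at 24 h, 0.0067% ± 0.000613 at 48 h, 0.00155% ± 0.000181 at 72 h and 0.00121% ± 0.0000593 at 96 h (SD, n = 3). The 47 took 0.143% ± 0.00124 at 0 h and 0.0106% ± 0.000252 at 24 h.

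The largest falls of any called model belonged to this later-falling group. SMED30014876 stood at 862 ± 11.6 RPKM at 0 h, 376 ± 3.03 at 24 h, 21.2 ± 3.16 at 48 h, 1.93 ± 0.307 at 72 h and 1.06 ± 0.163 at 96 h (SD, n = 3). Its mean RPKM was thus 2.29-fold lower at 24 h, 40.7-fold lower at 48 h and 817-fold lower at 96 h, the last from 13 to 28 reads per library. The log2 change at 96 h was -9.12 (SE 0.10, limma adjusted p = 6.61e-18), with 3 of 3 libraries below all 0 h libraries. SMED30002134 went from 663 ± 28.7 RPKM at 0 h to 283 ± 8.04 at 24 h, 15.3 ± 1.71 at 48 h, 1.37 ± 0.0403 at 72 h and 0.704 ± 0.0335 at 96 h. Its log2 change at 96 h was -9.11 (SE 0.06, limma adjusted p = 1.5e-20), from 8 to 13 reads per library. The changes of these 2 models could not be separated at 24, 48 or 72 h (no difference beyond 3 SE), and whether they share reads is open.

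**Figure D4:**
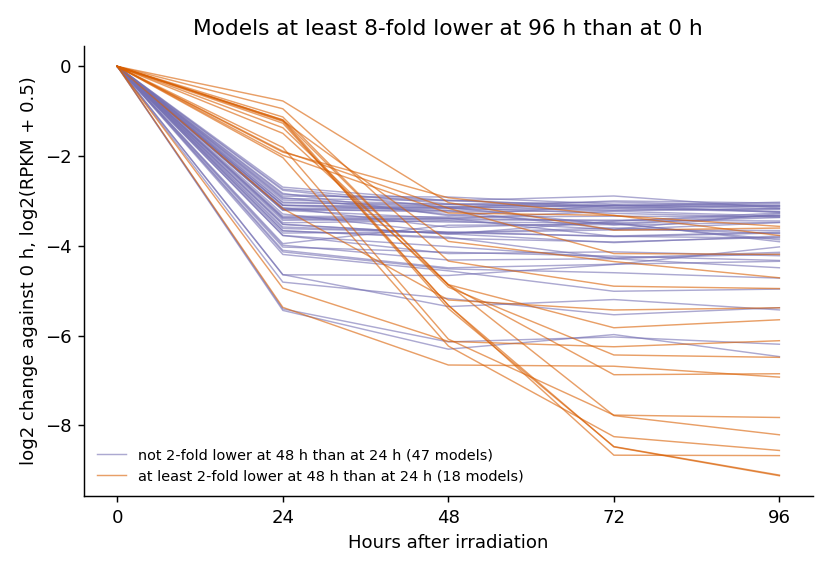
Log2 change against 0 h, on the log2(RPKM + 0.5) scale, of the 65 models at least 8-fold lower at 96 h than at 0 h, with a line for each model against hours after irradiation. The 18 models that fell at least 2-fold between 24 and 48 h (orange) reach a median of -6.30 at 96 h and the 47 others (purple), 34 of which had no room for a further 2-fold fall on this scale, -3.47.

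**Figure D5:**
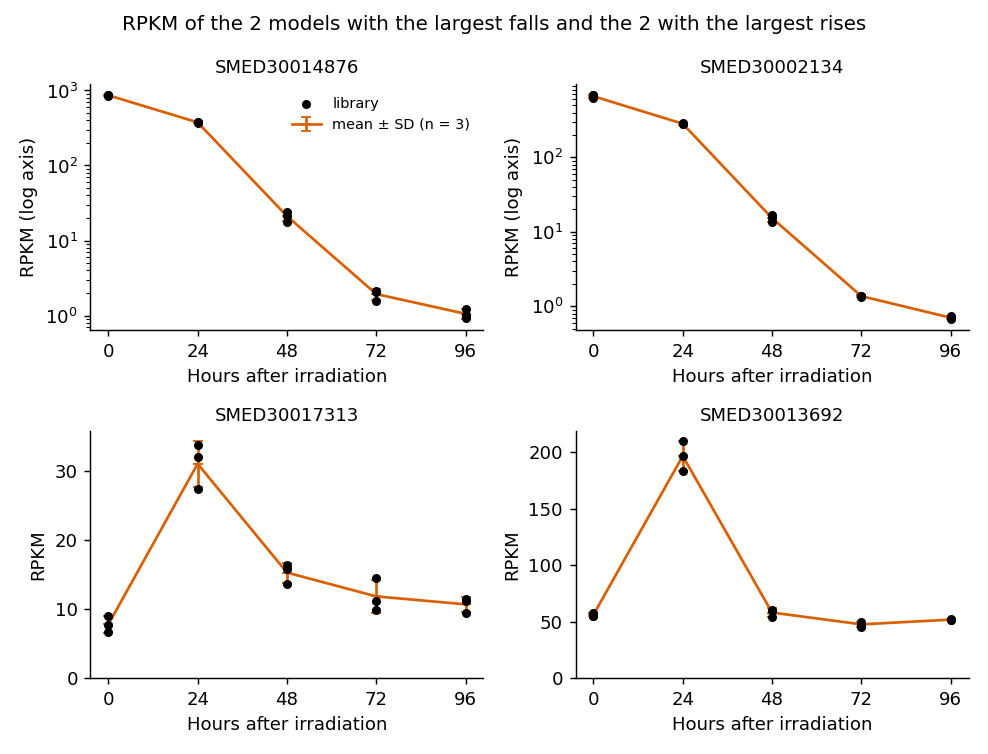
RPKM in each library (points) and mean with SD over 3 libraries (line and bars) against hours after irradiation for the 2 models with the largest falls (top, log axis) and the 2 with the largest rises (bottom, linear axis from 0). SMED30014876 goes from 862 to 1.06 RPKM, and SMED30013692 peaks at 197 RPKM at 24 h and stands at 58.2 RPKM at 48 h.

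Between 24 and 48 h, the largest changes were falls of models that had already declined. At least 2-fold falls were found in 25 models and at least 8-fold falls in 10, against 12 models with 2-fold rises. The 10 models together took 0.233% ± 0.00418 of reads at 0 h, 0.0935% ± 0.000756 at 24 h and 0.00553% ± 0.00066 at 48 h (SD, n = 3), and 9 of them had been at least 2-fold lower at 24 h than at 0 h. The 12 rising models had a median log2 change of -0.89 at 24 h and 0.19 at 48 h against 0 h. Regardless of size, 1444 models were higher and 1333 lower at 48 h than at 24 h (limma, adjusted p below 0.05), 89.3% of them by less than 1.5-fold. These counts fell to 931 and 842 without 48 h replicate 3, and the lower count to 888 without 24 h replicate 2. The 25 falls numbered 48 with a pseudocount of 0.1 RPKM and 63 with limma-voom.

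Between 48 and 72 h fewer models changed. At least 2-fold falls were found in 13 models, 9 of which were among the 25 that fell 2-fold between 24 and 48 h. The 13 took 0.0575% ± 0.00164 of reads at 48 h and 0.0256% ± 0.000406 at 72 h (SD, n = 3). Regardless of size, 87 models were higher and 297 lower at 72 h than at 48 h (limma, adjusted p below 0.05), so 22.7% of calls were rises. After quantile normalization 35.8% were rises (152 higher and 273 lower). Without 48 h replicate 1, 2 or 3 the higher count was 27, 51 or 32 and without 72 h replicate 1, 2 or 3 it was 152, 25 or 41. The lower count was 172 without 48 h replicate 1, 167 without 48 h replicate 2 and 192 without 72 h replicate 2, and the 13 falls became 20 without 72 h replicate 1.

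Between 72 and 96 h the changes were small, and 88.4% of called models changed by less than 1.5-fold. A total of 285 models were higher and 765 lower at 96 h than at 72 h (limma, adjusted p below 0.05), so 27.1% of calls were rises. After quantile normalization the share of rises was 43.9% (358 higher and 458 lower). The 18 later-falling models had a median log2 change of -0.05 between these times, after -3.38 between 24 and 48 h and -0.98 between 48 and 72 h. Without 72 h replicate 2 the counts were 49 higher and 307 lower. Without 96 h replicate 1 they were 121 and 474, without 96 h replicate 2 they were 55 and 329, and without 96 h replicate 3 they were 59 and 360.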

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

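The tests of the splits of 6 libraries, of a batch, of first-order decay and of few reads at 24 h were chosen after their results had been seen, as was the contrast of 96 h with 24 h. Each result in the next 2 paragraphs stood out because levels differed between time points in a direct limma contrast of the 2 times.

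SMED30014876 changed by -4.13 on the log2 scale from 24 to 48 h, by -3.15 from 48 to 72 h and by -0.64 from 72 to 96 h. SMED30002134 changed by -4.17, -3.07 and -0.64 over the same intervals. SMED30017313 changed by -0.996 from 24 to 48 h. SMED30013692 changed by -1.75 from 24 to 48 h and by -0.28 from 48 to 72 h. In addition, 303 models were called higher at 24 h and lower at 96 h than at 0 h, and 297 were called lower at 24 h and higher at 96 h. Their medians were 0.30 at 24 h and -0.30 at 96 h for the first set, and -0.25 and 0.28 for the second.

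The number of models that differed between neighbouring times was 2777 for 48 h and 24 h, 384 for 72 h and 48 h, and 1050 for 96 h and 72 h. For each of the 7 contrasts, 10 splits of the 6 libraries are too few for a share under 0.05, and in each 1 of 10 splits, the real one, gave as many calls. The highest other split gave 1 call against the real 8545 for 24 h and 0 h, and 1 against 9268 for 72 h and 0 h. For 48 h and 0 h it gave 0 against 8501, and for 96 h and 0 h 0 against 9542. The 3 neighbouring contrasts each had 0 calls in the highest other split. Every other split mixes libraries of both times within a group, so a real difference widens the spread there. These low counts thus do not give the number of calls expected by chance among like libraries. For the F test over the 5 time points, 1 of 100 groupings, the real one, gave as many as 11218 models and the highest other gave 5369. Chance is thus unlikely there, although 1 of 100 is the smallest share that so many groupings can give. The regrouping treats the libraries as independent, which the labels do not show.

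In the later fall of the 18 deep-falling models, few reads are argued against by models chosen without replicate 3 of 24 h and 48 h, since 17 of these 18 had an RPKM in replicate 3 under 0.5 times as high at 48 h as at 24 h, with a median ratio of 0.0662. A single first-order decay from 0 h would allow no larger fall in the second day than in the first. Of the 18, 12 exceeded that limit by more than 2 SE. The median excess over the 18 was -2.40 on the log2 scale, and -2.57 in a replicate held out of the choice. This argues against 1 such decay as the cause for those 12. The 18 were chosen for a fall between 24 and 48 h, so their share beyond the limit describes no other models. For the other 6, of which 4 fell by less than the limit by more than 2 SE, such a decay cannot be told apart from other courses. Of 153 pairs among the 18, 94.77% differed beyond 3 SE, but sharing of reads needs only a single partner, and the 8 pairs not separated, the named pair of falling models among them, hold 13 of the 18 models, so shared reads stay open. The group is also set by level, because 34 of the 47 other deep-falling models were too low at 24 h for a further 2-fold fall to be seen on this scale. Irradiation and elapsed time both stay open, no loss or change of cells was tested, and unirradiated worms beyond 0 h were not analysed here.

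The many small changes at 24 h are a further pattern, with 8545 calls of which 77.5% lie under 1.5-fold. Shallower 0 h libraries would make calls scarcer or noisier where reads are few. Of the 1515 models with at least 1000 reads in every library, 72.87% were called, against 40.25% of all tested models. A larger share is expected where reads are many, so this comparison does not decide on depth. With the reads thinned to the shallowest library, 6529 models were called at 24 h, so many calls did not need unequal depth. Length is argued against as a whole cause by 8646 calls after removal of each library's trend with length. Scaling between libraries is argued against as a whole cause of the number of calls by 8665 calls after quantile rescaling. Median of ratios rescaling gave 8552 calls, but it changed the scaling little (median change at 24 h of -0.000919 against -0.00776). The direction of calls did depend on scaling, with 4893 higher and 3772 lower after quantile rescaling against 4115 and 4430. A handling or library batch that sets the 0 h libraries apart cannot be told apart from irradiation, because 0 irradiated libraries were as shallow as the deepest 0 h library and no label names a batch. Irradiation and elapsed time both remain possible sources of these small changes.

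The decline of the 24 h rises by 96 h might arise from selecting high values at 24 h. Models chosen without replicate 3 of 0 h and 24 h numbered 64, and the held-out 24 h replicate lay a median of 0.4682 above the 96 h mean on the log2 scale, against 0.6163 in the replicates used to choose them, so selection explains part of the difference at most. Limma-voom on recovered reads called 41 of the 43 models higher at 24 h. It used the same libraries by which the 43 were chosen, so it cannot decide on noise of short models with few reads. A response to irradiation that lessens after 24 h therefore remains a hypothesis. A response to handling at the time of exposure stays open beside it, and these groups cannot separate them.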

How the results depend on the processing

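Limma-voom on recovered reads, thinning to the shallowest library and removal of the length trend were chosen after seeing the data. Of 735 recomputed counts, 604 stayed within 1.5 times the reported count and 131 moved. For the 4 named models, 268 recomputed changes kept their side of the threshold, 2 passed it and 2 no longer did. Among the 268, 1 change that was not called, that of SMED30013692 at 48 h, took the other sign after quantile normalization (limma adjusted p = 0.998). Calls against 0 h without a size limit moved by less than 1.5 times in all settings except the one that requires a 2-fold change. Median of ratios rescaling, robust moderation and length trend removal moved no count by over 1.5 times. The share of rises among calls against 0 h at 24, 48, 72 and 96 h went from 48.2%, 51.3%, 50.6% and 50.6% to 56.5%, 58.8%, 59.6% and 60.0% after quantile normalization. The edgeR test planned for recovered reads was not run, and limma-voom on these reads was used in its place. The set tests and the choice of a single model per gene name were not run because no names are paired with the IDs. Unless the construction of a setting shows it (fewer samples, fewer reads, a stricter threshold, another pseudocount for low levels), the cause was not tested.

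Pseudocount 0.1 RPKM gave first rises of 109, 37, 40 and 28 at 24, 48, 72 and 96 h, a 72 h first fall of 162 and 48 models 2-fold lower at 48 h than at 24 h. Pseudocount 1 RPKM gave first rises of 22, 4, 1 and 0; with it 0 models rose 2-fold at 96 h in limma. Without a filter, first rises at 96 h were 5. Quantile normalization gave first rises of 16, 20 and 8 at 48, 72 and 96 h, 152 models higher at 72 h than 48 h and 458 lower at 96 h than 72 h. Fits to the 6 libraries compared gave 8 higher and 110 lower for 72 h and 48 h, and 161 and 421 for 96 h and 72 h. Adjusted p below 0.01 gave 723 and 655 for 48 h and 24 h, 14 and 144 for 72 h and 48 h, and 41 and 278 for 96 h and 72 h.

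A required 2-fold change left 43 higher and 505 lower at 24 h, 25 and 549 at 48 h, 21 and 629 at 72 h, and 12 and 701 at 96 h against 0 h. It left 12 and 25 for 48 h and 24 h, 1 and 13 for 72 h and 48 h, 7 and 4 for 96 h and 72 h, and 924 models over the 5 time points.

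Voom gave first falls of 226 and 161 at 48 and 72 h, first rises of 83, 23, 28 and 32, 63 models 2-fold lower at 48 h than 24 h and 20 at 72 h than 48 h. It gave 260 higher and 460 lower for 72 h and 48 h, and 734 and 1166 for 96 h and 72 h. It called 89.6% of the models called at 24 h in the same direction, and 505 of 505 of the 2-fold falls as lower. Its 8-fold falls numbered 125 at 24 h and 174 at 96 h. Thinned reads gave a 48 h first fall of 211, first rises of 24, 22 and 16 at 48, 72 and 96 h, 888 and 797 for 48 h and 24 h, 44 and 171 for 72 h and 48 h, and 132 and 450 for 96 h and 72 h.

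Leaving out a library in turn gave first rises of 9 to 22 at 48 h, 12 to 28 at 72 h and 2 to 21 at 96 h. Counts for 48 h and 24 h ran from 931 to 1141 higher and 842 to 1068 lower. Those for 72 h and 48 h ran from 25 to 152 higher and 167 to 280 lower, with 12 to 20 models 2-fold lower. Those for 96 h and 72 h ran from 49 to 417 higher and 307 to 893 lower. The libraries that moved a count by over 1.5 times are named beside each count in the results above.

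Libraries of the same replicate number showed no clear pairing, although a weak one was not excluded. Deviations from the group means correlated at -0.063 to 0.11 between libraries of the same number and at -0.137 to 0.063 between others, and 6 of 15 libraries correlated best with their own number. With the replicate number as a block, 4101 models were higher and 4414 lower at 24 h, 4786 and 4673 at 96 h, and 11017 changed over the 5 time points. The block moved no count by over 1.5 times and changed no call of a named model. The later first rises lie at medians of 0.79, 0.59 and 0.36 RPKM at 0 h, near the pseudocount. Thinned reads gave more of these later rises, and 50 first rises at 24 h. The counts of the later rises thus grew with fewer reads, and counting noise at these low levels was not excluded. Thinning took the calls at 24 h from 8545 to 6529.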

Other observations

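The change at 24 h varied with the level of a model. When the tested models were divided into 5 equal groups by level, the median log2 change at 24 h was -0.07 in the lowest group and 0.11 in the highest, and at 96 h it was -0.02 and 0.10. Across 5 groups by length the medians at 24 h ran from 0.01 in the shortest to -0.04 in the longest. These are medians over models, which are not independent replicates.

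The number of models at or above 1 RPKM was 19924 ± 4.16 at 0 h and 19414 ± 63 at 24 h, 19406 ± 94.3 at 48 h, 19376 ± 164 at 72 h and 19496 ± 19 at 96 h (SD, n = 3). The most abundant model took 11.4% ± 0.381 of reads at 0 h and 10.4% ± 0.326 at 96 h, with no test made of this difference.

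The 7 models at least 2-fold higher at 96 h than at 72 h (limma, adjusted p below 0.05) had median log2 changes against 0 h of -0.33 at 24 h, 0.04 at 48 h, -0.66 at 72 h and 0.51 at 96 h. They took 0.0383% ± 0.0157 of reads at 48 h, 0.0245% ± 0.0104 at 72 h and 0.0522% ± 0.00488 at 96 h (SD, n = 3). The spread between libraries was wide at 48 and 72 h. The 7 were chosen for this rise in these same libraries.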
